A study of Mus musculus with 18 samples.

How the data were processed

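RNA-seq was deposited as 1 table of 10 libraries and H3K9me3 ChIP-seq as 1 peak list per immunoprecipitated library. Per the labels' protocols, RNA libraries were made from at most 5 ng of total RNA with SMART-Seq v4 amplification and Nextera tagmentation, which does not mark the strand, so genes that overlap on opposite strands cannot be told apart. The authors' deposited RNA values are FPKM, made with TopHat and Cufflinks on mm9 per the submitters' processing notes. Versions, the gene annotation and any filter are not given in the sources used here. The columns sum to 183632 to 504013, so they were not brought to a common total, and FPKM holds no read counts, so counting intervals were not computed. Per the labels' protocols the ChIP was native, with micrococcal nuclease digestion of nuclei from cultured CD8 T cells and an antibody to H3K9me3. The peaks were made with Bowtie and HOMER on mm9 per the submitters' processing notes, and per the file headers they were annotated against mm9. Each peak carries a score that the authors deposited; within a list all scores are whole multiples of 1 step, and the scaling of the score, the use of the input libraries and the calling threshold are not given in the sources used here. Scores served to rank and describe peaks, and their steps to read relative depth. Since their scaling is not given, scores of different lists compare only roughly: the mean score without satellite peaks was 20.8 and 25.3 in WT and 12.3 and 13.0 in KO. The region length is the deposited peak length in base pairs, per the file headers.

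Samples were grouped by the genotype and phenotype in their labels. The labels do not say whether samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. The 23700 lines of the RNA table held 23234 gene symbols; lines that repeat a symbol (466, from 250 symbols) were summed. Genes with a mean of at least 0.5 FPKM over the 10 libraries were tested (11162). Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) with a mean-variance trend, all 10 libraries sharing 1 spread (7 residual degrees of freedom), and Benjamini-Hochberg adjustment with a threshold of 0.05 in each of the 3 comparisons. A pseudocount of 1 understates the change of low genes. No rescaling was applied in the values reported first; the scaled values use size factors from the median ratio of each library to the geometric mean of all, on FPKM. Tests used no block. An added FPKM value of 1 is unrelated to any detection limit, which is unknown.

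The gene lists (22) were written from knowledge of T cells: helper lineage, Th1, Th2, Th17, follicular helper, regulatory, CD8 cytotoxic, terminal effector, naive and memory, inhibitory receptors, cell cycle, H3K9 methylation machinery, interferon response, germline and imprinted, immediate early and stress, and, as markers of other cells the samples could hold, thymocyte, B cell, myeloid, dendritic, NK cell, gamma-delta and innate-like T, and erythroid. Lists with at least 3 tested genes entered limma's camera with a preset correlation of 0.01 and again with an estimated one, and fry, adjusted over the 63 list tests. Counts cover the members that passed the filter, and are given over all genes tested and adjusted over the list alone. Some genes sit in more than 1 list (Maf, Il23r, Satb1, Tnfrsf4, Gata3 and others).

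Genes named in the text were chosen by rule. Ehmt2, Cd4, Cd8a, Cd8b1, Zbtb7b, Runx3, Cd40lg and Gata3 were always reported. Per comparison the 10 largest rises and 10 largest falls among called genes without overlap between the groups were eligible, passing over gene models without a symbol of their own, with up to 4 genes of each list by smallest p, and for H3K9me3 the helper list genes whose 2 libraries of a genotype both lay above the other. Genes named outside the rule were chosen after their values were seen: the abundant markers of the number ranges, Havcr2 and, in the peak lists, Rn45s, Krtap8-1 and Gm13251. The groups, tests, lists, this rule and most alternatives were fixed before the data were examined.

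KO DP and WT SP share the numbers 1 to 4 in the submitters' descriptions. Deviations from the group means correlated at 0.119, 0.293, 0.111 and 0.103 for the same numbers, each above 0.1. On that check alone the numbers were taken to pair the samples, though KO DP replicate 3 correlated best with WT SP replicate 4 and replicate 4 with 3. Samples of the same number also share a range of title numbers, so the check cannot tell pairing from a difference between the ranges. Relative depth of the RNA libraries was read from the ratios of low values between libraries, of which 50.7% to 75.8% were ratios of small whole numbers within a tolerance of 0.5%, against 19.7% by chance.

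For H3K9me3, covered lengths, overlaps (minimum 1 bp) and Jaccard indices were computed with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15. The plan called for gene bodies with 5 kb flanks, but no mm9 gene models were used here, so windows of 5 kb either side of gene starts took their place. Starts were derived from the lists' own distances to the nearest start: 15164 of the 18443 promoters in the lists could be placed, within 3 bp, and gave 13187 genes. The share of each window covered by peaks was tested with limma, 2 against 2. Random lists (10000) matched on mean expression gave percentiles, which describe these 4 libraries and are not tests.

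The scripts were tested on simulated data. In 100 genes shifted by a log2 change of 1 and 100 by 2, the RNA test recovered 17% and 87% for KO DP against WT SP (7 false calls), and 4% and 49% for each comparison with KO SP (2 and 3 false calls). In simulated windows 90.5% of 200 shifts of 20 percentage points were recovered, with 8 false calls among 5000 genes. The simulated noise was even (SD 4 percentage points). Real windows averaged 1.18% to 3.40% covered and many held no peak, so this recovery does not carry over to them. Alternatives covered the pseudocount, the filter, scaling, the trend, array weights, the libraries in the fit, blocks, number ranges and each library left out, and for peaks the score, the number, the overlap and the window. The input libraries were not used here. Figures were drawn with matplotlib 3.10.9.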

Results

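The series measured RNA and histone H3 lysine 9 trimethylation (H3K9me3), a mark of silent chromatin, in mouse T cells with and without G9a. G9a is a histone H3 lysine 9 methyltransferase encoded by Ehmt2. RNA was sequenced from T cells of spleen and lymph nodes that had expanded for 4 weeks in lymphocyte-poor surroundings. The RNA libraries fall into 3 groups: knockout CD4+CD8+ (double-positive) cells, called KO DP (n = 4), knockout cells with CD8 but not CD4, called KO SP (n = 2), and wild-type cells with CD8 but not CD4, called WT SP (n = 4). H3K9me3 was mapped in cultured CD8 T cells stimulated through CD3 and CD28, with 2 wild-type (WT) and 2 knockout (KO) libraries.

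The sum of FPKM, fragment counts scaled to gene length and library depth, ran from 441903 to 504013 in 8 of the 10 RNA libraries. It was 292872 in KO DP replicate 3 and 183632 in KO DP replicate 4. The same 2 libraries carried more signal over 1118 olfactory receptor genes, which T cells are not known to use: a mean of 0.149 and 0.227 FPKM, against at most 0.0210 in the other 8. Relative read depth, read from the steps of low values, ran from 0.799 to 1.57 times that of KO SP replicate 1, with KO DP replicate 3 at 1.19 and replicate 4 at 1.14. The library titles carry numbers in separate ranges, 34 to 37 (KO DP replicates 1 and 2, WT SP replicates 1 and 2) and 738 to 741 (all other libraries, so that KO SP occurs in the second range alone). Some red cell and macrophage transcripts, chosen after their values were seen, did not overlap between the ranges, both of which hold KO DP and WT SP. Hba-a1 (alpha globin) lay at 362 to 855 FPKM in titles 34 to 37 and at 0.207 to 47.7 in the others. C1qb (complement) lay at 12.4 to 42.1 against 0.601 to 4.14, and Lyz2 (lysozyme) at 19.1 to 44.3 against 2.74 to 13.9. Xist, transcribed from the inactive X chromosome, lay at 1.88 to 4.58 FPKM in the 6 knockout libraries and at most 0.0338 in the 4 wild-type ones.

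**Figure D1:**
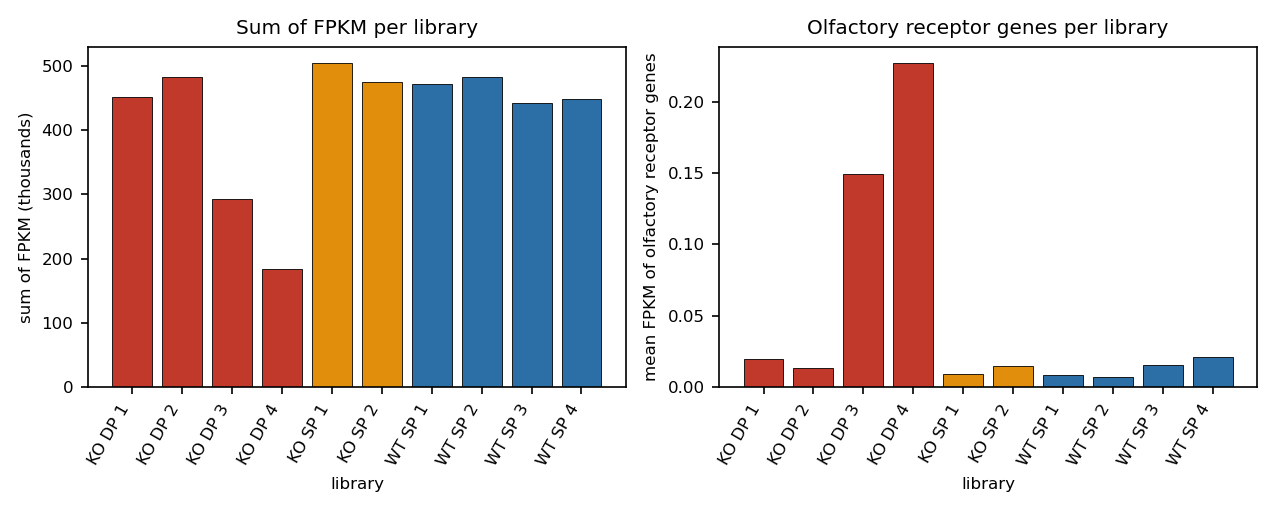
Bars give 1 value per RNA library, without error bars: on the left the sum of FPKM (in units of 1000), on the right the mean FPKM of the 1118 olfactory receptor genes (red, KO DP; orange, KO SP; blue, WT SP). KO DP replicates 3 and 4 had the lowest sums (292872 and 183632) and the highest olfactory receptor means (0.149 and 0.227 FPKM).

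Ehmt2, the targeted gene, was measured over its whole gene model, and the labels do not say which part was deleted, so its level is a limited check of genotype. Its FPKM was 20.9, 23.6, 12.8 and 7.28 in KO DP replicates 1 to 4, 12.6 and 13.6 in KO SP, and 18.1, 42.6, 27.0 and 21.6 in WT SP. The groups averaged 16.1 ± 7.48 (SD, n = 4), 13.1 ± 0.686 (n = 2) and 27.3 ± 10.8 (n = 4). Neither knockout group passed the test against WT SP: the log2 difference was -0.78 ± 0.38 (SE; adjusted p = 0.205, limma) for KO DP and -0.93 ± 0.46 (adjusted p = 0.938) for KO SP.

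The first comparison asked how knockout cells with both coreceptors differed from wild-type CD8 cells. Cd4, the helper coreceptor, averaged 110.3 ± 57.4 FPKM (SD, n = 4) in KO DP and 0.334 ± 0.173 in WT SP (n = 4), a log2 rise of 6.23 ± 0.36 (SE) on the log2(FPKM + 1) scale that all folds here use. Cd40lg, through which helper cells signal to B cells, rose by 4.08 ± 0.30, and Zbtb7b (ThPOK, the helper lineage factor) rose by 1.47 ± 0.34. Cd8b1, a chain of the CD8 coreceptor, averaged 590 ± 278 FPKM in KO DP and 1344 ± 144 in WT SP, a log2 difference of -1.33 ± 0.39 that missed the threshold. Cd8a (-0.92 ± 0.37), Runx3 (-0.63 ± 0.36), the cytotoxic lineage factor, and Gata3 (0.05 ± 0.37), a factor of helper commitment, did not pass either. Within titles 34 to 37 and 738 to 741 the log2 differences were 6.72 and 5.74 for Cd4, 4.50 and 3.66 for Cd40lg, and 1.93 and 1.00 for Zbtb7b. They were -0.64 and -2.02 for Cd8b1, -0.20 and -1.63 for Cd8a, -0.56 and -0.71 for Runx3, and 0.69 and -0.59 for Gata3. The adjusted p was 2.66e-06 for Cd4, 1.57e-05 for Cd40lg, 0.0253 for Zbtb7b, 0.0561 for Cd8b1, 0.144 for Cd8a, 0.263 for Runx3 and 0.932 for Gata3 (limma). The call of Zbtb7b ended without WT SP replicate 1 (adjusted p = 0.0733), 3 (0.0883) or 4 (0.0784). Cd8b1 passed without KO DP replicate 1 (adjusted p = 0.0313) or 4 (0.0441), with a block for the description number (0.0383) and after median-ratio scaling (-0.89, adjusted p = 0.00422), and Gata3 passed after scaling (0.47, adjusted p = 0.0300).

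**Figure D2:**
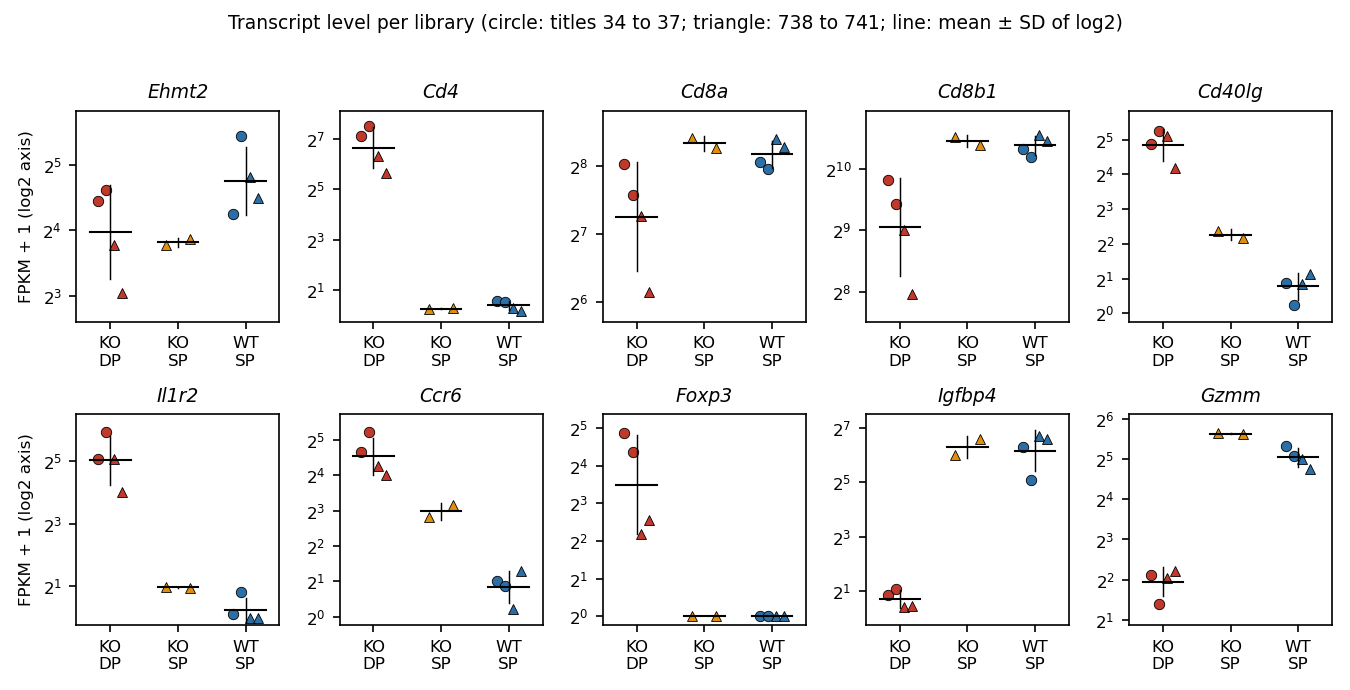
Each panel gives 1 gene as FPKM + 1 on a log2 axis whose range differs between panels, with 1 point per library (circles, titles 34 to 37; triangles, titles 738 to 741) and the mean ± SD of the log2 values as lines. Cd4 averaged 110.3 FPKM in KO DP and 0.334 in WT SP, and Igfbp4, a growth factor binding protein, 0.676 and 76.8 FPKM.

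In all, 881 of the 11162 genes tested changed between KO DP and WT SP, 319 higher and 562 lower. The median gene lay at -0.38, and scaling by median ratios, which removed this shift, gave 1952 calls, 1082 higher and 870 lower, so that the higher share went from 36.2% to 55.4%. Genes called both ways numbered 817 (319 higher, 498 lower). The median of all genes was 0.05 within titles 34 to 37 and -0.82 within 738 to 741, where 73 and 6015 genes were called. The difference between KO DP and WT SP itself differed between the ranges for 52 genes (limma interaction term; 4784 at an unadjusted p under 0.05), and for 37 after scaling (1580 unadjusted). Blocking on the description number gave 1375 calls, 617 higher and 758 lower, and on the number range 2123, 641 higher and 1482 lower. Limiting KO DP to replicates 1 and 2 gave 834 calls, 552 higher and 282 lower. The count was 394 without KO DP replicate 3, 527 and 525 without KO SP replicate 1 and 2, and 364, 308 and 348 without WT SP replicates 1, 3 and 4.

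Among the largest rises with no overlap were receptors and secreted factors. Il1r2, the decoy receptor of interleukin 1, averaged 34.8 ± 18.4 FPKM in KO DP and 0.214 ± 0.376 in WT SP (log2 rise 4.78 ± 0.37, adjusted p = 1.89e-05). Penk, the precursor of enkephalin peptides, rose by 4.75 ± 0.56, Gtsf1, a small RNA pathway factor of germ cells, by 4.32 ± 0.32, and Tnfrsf4 (OX40, a costimulatory receptor) by 4.22 ± 0.40. Hrh4, a histamine receptor, rose by 4.18 ± 0.31, Tff1, a trefoil peptide, by 4.17 ± 0.59, Folr4, a folate receptor family member abundant on regulatory T cells, by 3.85 ± 0.55, and Ccr6, a chemokine receptor, by 3.70 ± 0.32. Their adjusted p ran from 1.57e-05 (Hrh4) to 0.00186 (Folr4). Among the largest falls, Igfbp4, an insulin-like growth factor binding protein, went from 76.8 ± 31.5 FPKM in WT SP to 0.676 ± 0.372 in KO DP (log2 -5.44 ± 0.37, adjusted p = 8.20e-06). Plac8 (-5.28 ± 0.40), Aqp9, a water and glycerol channel (-4.79 ± 0.37), and G0s2, a lipase inhibitor (-4.02 ± 0.26), fell as well. After scaling these 4 falls were -5.20, -4.89, -4.52 and -3.76, and the rises of Il1r2, Penk, Tnfrsf4 and Ccr6 were 5.07, 5.09, 4.62 and 4.03. Y-linked Eif2s3y (-5.00 ± 0.21) and Ddx3y (-4.34 ± 0.23) were also among the largest falls. Surf2 was listed at 0 in all 4 KO DP libraries and at 37.5, 29.8, 48.0 and 53.7 FPKM in WT SP. Cd72 was listed at 0, 0, 4.08 and 7.002 against 61.5, 26.0, 96.9 and 96.8 FPKM, and Pusl1 at 0, 0, 0 and 8.83 against 24.9, 14.97, 41.5 and 42.5. An exact 0 of a commonly used gene such as Surf2 can be a failed estimate.

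As deposited, some genes of each helper list but Th1 rose. Of the 12 genes of the Th17 list (the interleukin 17 helper lineage), Il17a and Il22 lay below the filter and were not tested. The other 10 all rose, with a list median of 2.60. They included Ccr6 and a pair of membrane proteins, Tmem176a (3.26 ± 0.33) and Tmem176b (3.24 ± 0.31). Il23r was listed at 0 in all 4 WT SP libraries and at 1.03, 1.73, 0.676 and 1.02 FPKM in KO DP. Of 11 regulatory T cell genes 9 rose and 2 were not called (median 2.24). Tnfrsf4, Folr4, and Ebi3 (2.24 ± 0.31), a cytokine subunit, were higher. Foxp3, the lineage factor, was listed at 0 in all WT SP and KO SP libraries and at 28.3, 19.8, 3.52 and 4.94 FPKM in KO DP (adjusted p = 0.00188). Of 10 general helper lineage genes 6 rose and 4 were not called (median 1.698), among them Cd4, Tnfrsf4 and Cd40lg. Of 8 Th2 genes 4 rose and 4 were not called (median 1.51): Penk, the chemokine receptors Ccr8 (2.996 ± 0.39) and Ccr4 (2.69 ± 0.31), and the factor Maf (1.80 ± 0.32). Only these 8 of the 20 listed Th2 genes passed the filter. Il4, Il5, Il13 and Il9 were among those below it. Of 12 follicular helper genes 4 rose, 1 fell and 7 were not called (median 1.11): Cd200 (2.62 ± 0.40), the cytokine Il21 (2.59 ± 0.43) and the costimulator Icos (1.93 ± 0.33) rose, and Il6st, the shared receptor chain of interleukin 6, fell (-2.10 ± 0.39). Of 9 Th1 genes none rose, 1 fell and 8 were not called (median -0.63), and after scaling 1 rose and 2 fell. The fall as deposited was in Il12rb2, a receptor chain of interleukin 12 (-1.03 ± 0.25, adjusted p = 0.0302). It did not pass after scaling (-0.65, adjusted p = 0.148), nor without KO DP replicate 2 (adjusted p = 0.0598), KO SP replicate 1 (0.0541) or 2 (0.0544), or WT SP replicate 1 (0.0665), 2 (0.0522), 3 (0.0848) or 4 (0.0991). Of 6 gamma-delta and innate-like T cell genes 4 rose and 2 were not called (median 1.43), among them Cd163l1 (2.82 ± 0.40), a scavenger receptor of gamma-delta T cells, with Maf and Il23r, which other lists also hold. Without WT SP replicate 1 or 3, 5 regulatory genes rose, and without WT SP replicate 2, 3 follicular helper genes fell and 1 Th1 gene rose.

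Adjusted over the list alone, the counts were 10 of 10 higher for Th17, 9 for regulatory T cells, 6 for helper lineage, 4 for Th2, 6 higher and 3 lower for follicular helper, 1 lower for Th1 and 4 higher for gamma-delta. The camera test with a preset correlation placed the Th17 (adjusted p = 1.99e-23), regulatory (8.57e-17), helper lineage (1.01e-12), gamma-delta (6.39e-08), Th2 (3.02e-09) and follicular helper (3.91e-05) lists above other genes, but not Th1 (0.857). Each call was lost when the correlation was estimated: adjusted p = 0.165 with an estimated correlation for Th17, regulatory, helper lineage, gamma-delta and Th2, and adjusted p = 0.320 with an estimated correlation for follicular helper. With fry, which asks whether the genes of a list move on balance one way, the adjusted p was 0.00113 for Th17, 0.00788 for helper lineage, 0.0119 for regulatory, 0.0122 for gamma-delta, 0.0219 for Th2, 0.139 for follicular helper and 0.453 for Th1. Within titles 34 to 37 and 738 to 741 the list medians were 2.78 and 2.21 for Th17, 2.797 and 1.68 for regulatory, 2.04 and 1.36 for helper lineage, 2.20 and 1.37 for Th2, 1.60 and 0.71 for follicular helper, -0.25 and -0.92 for Th1, and 1.75 and 1.10 for gamma-delta. After scaling the medians over all libraries were 2.92, 2.496, 2.01, 1.63, 1.53, -0.19 and 1.60 in that order.

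Genes of resting T cells fell. Of 12 naive and memory genes 9 fell and 3 were not called (median -1.54, -1.10 after scaling), among them Ccr7, a chemokine receptor of naive T cells (-3.55 ± 0.40, adjusted p = 0.000399), Bcl2, a survival factor (-3.09 ± 0.44), and Satb1, a chromatin organiser (-2.51 ± 0.32). Of 18 CD8 cytotoxic genes 1 rose, 3 fell and 14 were not called (median -0.88, -0.44 after scaling): the granule protease Gzmm went from 32.1 ± 5.40 to 2.97 ± 0.897 FPKM (-3.08 ± 0.26), and the receptor chain Klrd1 (-1.704 ± 0.29) fell. Ctsw, a cathepsin of cytotoxic cells (-1.29 ± 0.32, adjusted p = 0.0304), did not pass without KO DP replicate 3 (adjusted p = 0.108), KO SP replicate 1 (0.0601) or 2 (0.0606), or WT SP replicate 1 (0.0630), 3 (0.119) or 4 (0.114), and Itgae, the CD103 integrin chain (2.25 ± 0.48, adjusted p = 0.0163), did not pass without WT SP replicate 3 (0.0620). Of 20 cell cycle genes 3 rose and 17 were not called (median 1.58, 1.95 after scaling), the mitotic cyclin Ccnb1 (2.12 ± 0.51, adjusted p = 0.0291), the nucleotide reductase subunit Rrm2 (1.92 ± 0.50, adjusted p = 0.0375) and the kinase Cdk1 (1.69 ± 0.47, adjusted p = 0.0475). After scaling 14 of the 20 rose. Without KO DP replicates 2 and 3 the adjusted p of Ccnb1, Rrm2 and Cdk1 was 0.0536, 0.0668 and 0.0806, and 0.107, 0.137 and 0.161. Without WT SP replicates 1, 3 and 4 it was 0.0691, 0.0734 and 0.101, then 0.108, 0.134 and 0.161, then 0.0964, 0.123 and 0.147. Without KO DP replicate 4 it was 0.0682 for Ccnb1 and 0.0710 for Cdk1, and without KO SP replicates 1 and 2 it was 0.0503 and 0.0505 for Rrm2 and 0.0604 and 0.0606 for Cdk1. The falls of the naive and memory list numbered 5 without KO DP replicate 3, KO SP replicate 1 or 2, or WT SP replicate 1, 3 or 4. Without KO DP replicate 1, 6 cytotoxic genes fell and 6 cell cycle genes rose; without WT SP replicate 2, 2 cytotoxic and 12 cell cycle genes rose.

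Of 13 terminal effector genes 0 were called by limma (median 0.53; 3 after scaling). Of 11 inhibitory receptor genes 1 rose and 10 were not called (median 1.0499): Ctla4, which restrains T cell activation (3.08 ± 0.67, adjusted p = 0.0192), a call that ended without KO DP replicate 3 (adjusted p = 0.0514) or WT SP replicate 1 (0.0652), 3 (0.0774) or 4 (0.0668). WT SP replicate 2 lay above the other WT SP libraries at 10 of these 11 genes, and without it 7 were called, all higher, among them Pdcd1 (PD-1; 4.94 ± 0.45, adjusted p = 0.000124; 3.39 and 0.0944 with it) and Tigit (4.197 ± 0.72, adjusted p = 0.00550; 3.06 and 0.0875 with it). Of 18 genes of the H3K9 methylation machinery 0 were called by limma (median -0.43). Of 20 interferon response genes 1 fell, Usp18, which dampens interferon signalling (-1.95 ± 0.39, adjusted p = 0.0120; 0.0536 without WT SP replicate 3), and 19 were not called (median -0.30). Of 13 immediate early and stress genes Egr2 rose (2.12 ± 0.42, adjusted p = 0.0119; 0.0526 without WT SP replicate 3), Myc fell (-2.60 ± 0.40, adjusted p = 0.00293) and 11 were not called (median -0.38). Of 5 thymocyte genes 1 rose, 1 fell (Satb1) and 3 were not called (median -0.53). The falls became 3 for immediate early, 2 for thymocyte and 1 for H3K9 machinery genes without KO DP replicate 1. The rises became 2 for immediate early and 1 for terminal effector genes without KO DP replicate 4, and again without WT SP replicate 2. Adjusted over the list alone, 11 naive and memory genes were lower, 1 cytotoxic gene higher and 6 lower, 13 cell cycle genes higher, 4 inhibitory receptor genes higher, 3 immediate early genes higher and 2 lower, 1 interferon gene lower, 1 thymocyte gene higher and 2 lower, and 0 for terminal effector and H3K9 machinery. After scaling, over all genes, 11 naive and memory genes were lower, 1 cytotoxic gene higher and 5 lower, and 3 inhibitory receptor genes higher. The same scaling gave 1 H3K9 machinery gene lower and 1 interferon gene higher and 1 lower. It also gave 3 immediate early genes higher and 2 lower, and 1 thymocyte gene higher and 2 lower. By camera the naive and memory list lay below other genes (adjusted p = 5.32e-07; adjusted p = 0.408 with an estimated correlation; fry 0.0119). The cell cycle (1.72e-14), inhibitory receptor (1.62e-05) and terminal effector (0.00132) lists lay above them (adjusted p = 0.323, 0.524 and 0.694 with an estimated correlation). The adjusted p was 0.150 for CD8 cytotoxic, which after scaling lay below other genes (0.0372; adjusted p = 0.520 with an estimated correlation), 0.800 for H3K9 machinery, 0.747 for interferon, 0.411 for immediate early and 0.914 for thymocyte genes. Within titles 34 to 37 and 738 to 741 the medians were -0.74 and -2.11 for naive and memory, -0.49 and -1.25 for cytotoxic, 0.74 and 2.30 for cell cycle, 0.57 and 0.42 for terminal effector, 1.03 and 1.498 for inhibitory receptors, -0.08 and -0.76 for H3K9 machinery, 0.41 and -1.16 for interferon, 0.08 and -0.84 for immediate early, and 0.19 and -1.28 for thymocyte genes.

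**Figure D3:**
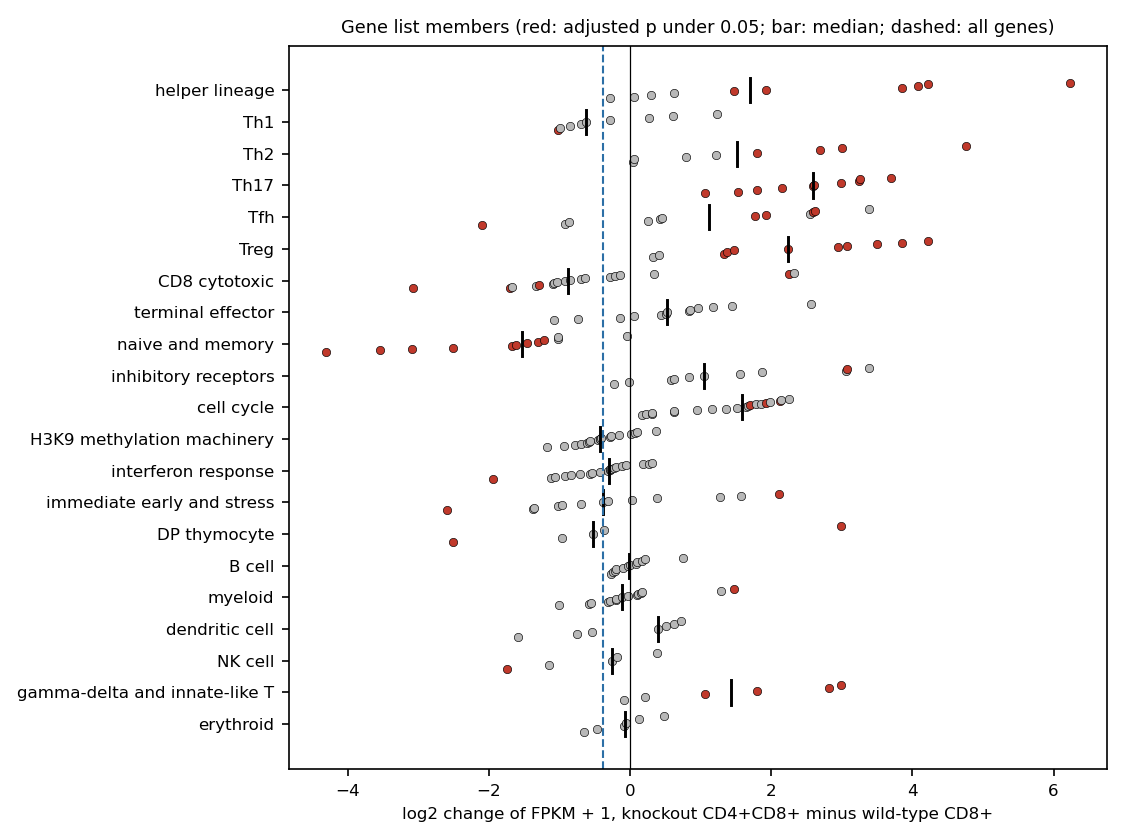
Each point is 1 tested gene of a list, placed by its log2 change of FPKM + 1 between KO DP (n = 4) and WT SP (n = 4). Red points had an adjusted p under 0.05, black bars give list medians and the dashed line the median of all genes (-0.38). The Th17 list had the highest median (2.60) and the naive and memory list the lowest (-1.54).

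Markers of other cell types were mostly uncalled in this comparison, apart from the gamma-delta and innate-like T list above, of which 4 of 6 genes rose. Of 12 B cell genes 0 were called by limma (median -0.02) and of 6 erythroid genes 0 (median -0.08). Of 15 myeloid genes Cybb, an oxidase subunit of phagocytes, rose (1.47 ± 0.33, adjusted p = 0.0204; 0.0687 without WT SP replicate 1 and 0.0768 without replicate 3) and 14 were not called (median -0.12). Of 7 dendritic cell genes 0 were called by limma (median 0.40, mean -0.09). Of 5 NK cell genes Klra3, an inhibitory receptor, fell (-1.74 ± 0.38, adjusted p = 0.0196; 0.0708 and 0.0565 without KO DP replicates 3 and 4, 0.0627 without WT SP replicate 1) and 4 were not called (median -0.25). Adjusted over the list alone, the counts were 0 for B cell and erythroid, 1 higher for myeloid, 1 higher and 1 lower for dendritic and 1 lower for NK cell. The camera adjusted p was 0.131 for B cell, 0.0924 for myeloid, 0.0866 for dendritic, 0.914 for NK cell and 0.337 for erythroid genes. Within titles 34 to 37 and 738 to 741 the medians were 0.70 and -0.64, 0.39 and -0.37, 0.01 and 0.42, -0.71 and -0.74, and 0.11 and -0.22 in the same order. Of the germline and imprinted genes fewer than 3 passed the filter, so that list was not tested.

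The second comparison held the CD8 phenotype fixed and set knockout against wild type. The groups also differed in Xist and Y-linked genes, so genotype cannot be told from sex here. Cd163l1, the gamma-delta scavenger receptor, averaged 101 ± 3.21 FPKM in KO SP (n = 2) and 4.698 ± 1.53 in WT SP (n = 4), a log2 rise of 4.202 ± 0.49. Gtsf1 rose by 3.79 ± 0.40, Gpm6b, a membrane glycoprotein of the proteolipid family, by 2.69 ± 0.39 and Gabrr2, a GABA receptor subunit, by 2.31 ± 0.35. Cd4 stayed near 0 in both groups, at 0.207 ± 0.0211 and 0.334 ± 0.173 FPKM (log2 -0.14 ± 0.44, adjusted p = 0.980). Xist rose by 1.72 ± 0.27, and the Y-linked genes Eif2s3y (-5.12 ± 0.26), Ddx3y (-4.48 ± 0.28), Kdm5d (-3.05 ± 0.30) and Uty (-2.96 ± 0.24) fell. Within titles 738 to 741 the values were 4.13 for Cd163l1, 4.08 for Gtsf1, 2.71 for Gpm6b, 2.14 for Gabrr2 and 1.73 for Xist.

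The test called 13 genes, 8 higher and 5 lower, and 384 had an unadjusted p under 0.05. After scaling, which moved the median from 0.11 to 0.01, 20 were called, 15 higher and 5 lower, so that the higher share went from 61.5% to 75%. Gabrr2 (adjusted p = 0.0849) and Xist (0.0796) were then not called and Ccr6 was (1.95, adjusted p = 0.0339; as deposited 2.13 ± 0.40, adjusted p = 0.108). The remaining fall was Rbm12, listed at 0 in both KO SP libraries and at 13.9, 17.8, 13.3 and 9.48 FPKM in WT SP, an exact 0 that can be a failed estimate as well. The calls of Gtsf1 and of the 4 Y-linked genes held without any 1 library. Without KO SP replicates 1 and 2 the adjusted p was 0.0799 and 0.0635 for Cd163l1, 0.0799 and 0.0630 for Rbm12, 0.350 and 0.280 for Gpm6b, 0.350 and 0.315 for Gabrr2, and 0.185 and 0.504 for Xist. The call of Gpm6b also ended without KO DP replicate 3 (adjusted p = 0.0659) or WT SP replicates 2 (0.0662), 3 (0.0963) and 4 (0.0820), and that of Gabrr2 without KO DP replicates 3 (0.0707) and 4 (0.0576) or WT SP replicates 3 (0.0973) and 4 (0.0686). For Xist the adjusted p was 0.0523 and 0.0637 without KO DP replicates 1 and 3, and 0.0995, 0.0734, 0.145 and 0.112 without WT SP replicates 1, 2, 3 and 4.

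Of the genes that rose in KO DP, several lay higher in KO SP without passing the test. Folr4 differed by 2.51 ± 0.67 (adjusted p = 0.479), Tmem176a by 1.51 ± 0.40 (0.443), Cd40lg by 1.49 ± 0.37 (0.333) and Tmem176b by 1.12 ± 0.38 (0.938). Of the 10 Th17 genes 0 were called over all genes and 4 were higher when adjusted over the list alone (median 0.79); camera placed the list above other genes (adjusted p = 3.15e-06; adjusted p = 0.323 with an estimated correlation). Of the 6 gamma-delta genes 1 rose, Cd163l1 (none without KO SP replicate 1 or 2), and 3 were higher adjusted over the list alone (median 0.81; camera 7.27e-05, adjusted p = 0.323 with an estimated correlation). The cell cycle list lay above other genes (median 0.84; camera 4.03e-06, adjusted p = 0.635 with an estimated correlation; 0.0671 without KO SP replicate 1). The terminal effector list did so as well (median 0.58; camera 0.0366, adjusted p = 0.844 with an estimated correlation), but not without KO DP replicate 4 (0.191), KO SP replicate 1 (0.941) or WT SP replicates 3 (0.400) and 4 (0.169). So did CD8 cytotoxic (median 0.33; camera 0.0370, adjusted p = 0.844 with an estimated correlation), but not after scaling (0.134) nor without KO DP replicate 4 (0.155), KO SP replicate 1 (0.595) or WT SP replicates 3 (0.164) and 4 (0.0764). The interferon list was above other genes too (median 0.47; camera 0.0215, adjusted p = 0.844 with an estimated correlation), but not without KO SP replicate 1 (0.145) or WT SP replicates 1 (0.0542) and 2 (0.220). The H3K9 machinery list lay below other genes (median -0.29; camera 0.00483, adjusted p = 0.822 with an estimated correlation), and so did the myeloid list (median -0.81; camera 0.000253, adjusted p = 0.649 with an estimated correlation), whose transcripts also differed between the number ranges. No gene of these lists other than Cd163l1 was called.

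The remaining lists did not pass camera between KO SP and WT SP. They were helper lineage (median 0.14, adjusted p = 0.146; 2 genes higher adjusted over the list alone), regulatory (0.42, 0.152; 1 higher) and NK cell (0.36, 0.747; 1 higher). With 0 genes either way, they were Th1 (0.22, 0.178), Th2 (0.03, 0.793), follicular helper (0.31, 0.340), naive and memory (0.04, 0.599), inhibitory receptors (0.18, 0.769), immediate early (0.14, 0.914), thymocyte (-0.03, 0.816), B cell (-0.11, 0.309), dendritic (0.09, 0.917) and erythroid (-1.92, 0.144). The other always-reported genes had log2 differences of 0.16 ± 0.46 for Cd8a, 0.07 ± 0.47 for Cd8b1, -0.22 ± 0.42 for Zbtb7b, -0.38 ± 0.44 for Runx3 and -0.03 ± 0.45 for Gata3, with adjusted p of 0.938 (Runx3) to 1 (Gata3). The sign of each, and that of Cd4, turned under at least 1 alternative.

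The third comparison set double-positive against CD8 cells within the knockout, and it is the test of the difference between the first and second. Cd4 rose by 6.37 ± 0.44 (SE; n = 4 against 2), Tnfrsf4 by 4.18 ± 0.49, Il1r2 by 4.04 ± 0.46, Scin, an actin-severing protein, by 3.14 ± 0.26, and Tnfsf11 (RANKL) by 2.996 ± 0.33. Igfbp4 (-5.57 ± 0.45), Plac8 (-5.06 ± 0.49), Aqp9 (-4.91 ± 0.46), G0s2 (-3.73 ± 0.31), Gzmm (-3.67 ± 0.32) and Cnr2, a cannabinoid receptor (-3.63 ± 0.41), fell. The adjusted p of these 11 genes ran from 4.16e-05 (Cd4) to 0.00147 (Tnfrsf4), and each call held without any 1 library. Within titles 738 and 739, the only ones with KO SP, the differences were 5.72 for Cd4, 3.69 for Tnfrsf4, 3.56 for Il1r2, 3.05 for Scin, 2.58 for Tnfsf11, -5.83 for Igfbp4 and -3.48 for Gzmm. Foxp3 was listed at 0 in both KO SP libraries and was called higher in KO DP (adjusted p = 0.0163), as was Rbm12 (0.00237). Surf2, listed at 0 in KO DP, stood at 44.2 and 51.6 FPKM in KO SP. Ehmt2 (0.16 ± 0.46, adjusted p = 0.851), Cd8a (-1.08 ± 0.46, 0.189), Cd8b1 (-1.40 ± 0.47, 0.126), Zbtb7b (1.69 ± 0.42, 0.0621), Runx3 (-0.26 ± 0.44, 0.728) and Gata3 (0.08 ± 0.45, 0.923) did not pass. After scaling Cd8b1 (-0.84, adjusted p = 0.0301), Zbtb7b (1.89, 0.00557) and Gata3 (0.62, 0.0495) did, as did Zbtb7b without KO DP replicate 4 (0.0304). Without KO SP replicates 1 and 2 the adjusted p of Foxp3 was 0.217 and 0.224 and that of Rbm12 0.0580 and 0.0726.

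In all 231 genes changed, 47 higher and 184 lower; a block for the number range gave 468, 90 higher and 378 lower. The median of all genes was -0.43; scaling gave 606 calls, 292 higher and 314 lower (higher share 48.2%, against 20.3%), and 194 genes were called both ways (47 higher, 147 lower). The count was 24 and 21 without KO SP replicate 1 and 2, 141, 96 and 401 without KO DP replicates 2, 3 and 4, and 126, 145 and 144 without WT SP replicates 1, 3 and 4; limiting KO DP to replicates 1 and 2 gave 460 (267 higher, 193 lower).

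Some helper genes rose in this comparison too. Of 10 helper lineage genes 3 rose (5 adjusted over the list alone; median 1.41), Cd4, Tnfrsf4 and Cd40lg (2.59 ± 0.37, adjusted p = 0.00488). Of 8 Th2 genes 4 rose (4 adjusted over the list alone; median 1.60), among them Penk (4.64 ± 0.69, 0.00595). Of 10 Th17 genes 4 rose (10 adjusted over the list alone; median 1.65), among them Ahr, a ligand-sensing transcription factor (1.97 ± 0.35, 0.0163), and Tmem176b (2.12 ± 0.38, 0.0163). Of 11 regulatory genes 3 rose (6 adjusted over the list alone; median 1.55), among them Ebi3 (2.40 ± 0.38, 0.00810). Of 12 follicular helper genes 1 rose, 4 being higher and 3 lower adjusted over the list alone (median 0.73). Without KO SP replicate 1 the adjusted p was 0.0831 for Cd40lg, 0.118 for Penk, 0.249 for Ahr, 0.218 for Tmem176b and 0.152 for Ebi3, and without KO SP replicate 2 it was 0.121, 0.108, 0.175, 0.246 and 0.123. With KO SP replicate 1 or 2 left out, 2 helper lineage genes and 1 regulatory gene rose, and 0 Th2, Th17 and follicular helper genes were called by limma. The 4 Th2 genes became 2 without KO DP replicate 2 or 3. The 4 Th17 genes became 2 without KO DP replicate 3 or WT SP replicates 1 or 3, and 7 without KO DP replicate 4, where helper lineage genes numbered 5 and follicular helper genes 2. The follicular helper gene, Il21, did not pass without KO DP replicate 3 or WT SP replicates 1 or 3. Without WT SP replicate 2, 6 regulatory and 4 follicular helper genes rose. By camera these lists lay above other genes (helper lineage 2.07e-11, Th2 1.82e-09, Th17 1.43e-17, regulatory 6.99e-14, follicular helper 0.000595); adjusted p = 0.165 with an estimated correlation for the first 4 and adjusted p = 0.389 with an estimated correlation for follicular helper.

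Of 12 naive and memory genes 4 fell (10 adjusted over the list alone; median -1.54, camera 2.05e-06; adjusted p = 0.441 with an estimated correlation), among them Ccr7 (-3.60 ± 0.49, adjusted p = 0.00379) and Satb1 (-2.48 ± 0.39, 0.00803). Without KO SP replicates 1 and 2 the adjusted p was 0.0713 and 0.105 for Ccr7 and 0.116 and 0.176 for Satb1. Of 18 CD8 cytotoxic genes 2 fell (8 adjusted over the list alone; median -1.04, camera 0.00570; adjusted p = 0.706 with an estimated correlation, and 0.0893 without KO SP replicate 1), among them Gzmm. Of 6 gamma-delta genes 1 rose (3 higher and 2 lower adjusted over the list alone; median 0.43, camera 0.0168; adjusted p = 0.599 with an estimated correlation, 0.0558 without KO SP replicate 1). The inhibitory receptor (median 1.66, camera 8.56e-06; adjusted p = 0.512 with an estimated correlation) and cell cycle lists (median 0.60, camera 3.45e-05; adjusted p = 0.672 with an estimated correlation, 0.0893 without KO SP replicate 2) lay above other genes with 0 genes called by limma, over all genes or over the list alone. So did the B cell list (median 0.12, camera 0.0285; adjusted p = 0.841 with an estimated correlation), but not without KO DP replicates 1 (0.0553) and 4 (0.201) or KO SP replicate 1 (0.443). The erythroid list did too (median 1.72, camera 0.0463; adjusted p = 0.758 with an estimated correlation), but not without KO DP replicates 2 (0.135) and 4 (0.111) or KO SP replicate 2 (0.149). Of 15 myeloid genes 1 rose (1 adjusted over the list alone; median 0.91, camera 1.62e-05; adjusted p = 0.599 with an estimated correlation). Hba-a1 of the erythroid list and C1qb and Lyz2 of the myeloid list were higher in titles 34 to 37, a range that holds KO DP but not KO SP. The lists themselves were not tested between the ranges. With KO SP replicate 1 or 2 left out, 1 naive and memory and 1 cytotoxic gene fell and 0 gamma-delta and myeloid genes were called by limma. The cytotoxic falls were 1 without KO DP replicates 2 or 3 or WT SP replicates 1, 3 or 4, and 4 without KO DP replicate 1. The myeloid rise, Cybb (adjusted p = 0.0393), ended without KO DP replicates 1 (0.0541), 2 (0.0520) and 3 (0.0651), KO SP replicates 1 (0.365) and 2 (0.363), and WT SP replicates 1 (0.0700), 3 (0.0642) and 4 (0.0633). The gamma-delta rise, Maf (0.0366), ended without KO DP replicate 2 (0.0507), KO SP replicates 1 (0.318) and 2 (0.367), and WT SP replicates 1 (0.0637), 3 (0.0591) and 4 (0.0580), and 2 rose without KO DP replicate 4. Without KO DP replicate 1, 1 gamma-delta gene fell, and without WT SP replicate 2, 2 inhibitory receptor genes rose.

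The lists that did not pass camera in this comparison were Th1 (median -0.87, adjusted p = 0.297; 4 lower adjusted over the list alone), terminal effector (-0.17, 0.191), H3K9 machinery (-0.09, 0.136), interferon (-0.83, 0.0684; 1 fell, Usp18, and 2 were lower adjusted over the list alone), immediate early (-0.60, 0.550; 1 fell, Myc, and 1 was higher and 1 lower adjusted over the list alone), thymocyte (-0.64, 0.938; 1 fell, Satb1, and 1 was higher and 1 lower adjusted over the list alone), dendritic (0.10, 0.117; 1 lower adjusted over the list alone) and NK cell (-0.70, 0.572). After scaling the H3K9 machinery list lay above other genes (adjusted p = 0.0383; adjusted p = 0.673 with an estimated correlation) and the interferon list below them (0.0456; adjusted p = 0.726 with an estimated correlation). The B cell (0.128), gamma-delta (0.132) and erythroid (0.726) lists then no longer passed. The fall of Usp18 (adjusted p = 0.0177) ended without KO DP replicate 3 (0.0593) or KO SP replicates 1 (0.258) and 2 (0.220), and that of Myc (0.0390) without KO DP replicate 3 (0.112), KO SP replicates 1 (0.319) and 2 (0.391), or WT SP replicates 1 (0.0703), 3 (0.0635) and 4 (0.0650). Satb1 did not pass with KO SP replicate 1 or 2 left out. The interferon falls became 2 without KO DP replicate 1, and again without WT SP replicate 2. Without KO DP replicate 4, 1 thymocyte and 1 immediate early gene rose and 1 Th1 gene fell, and without WT SP replicate 2, 1 dendritic gene fell.

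Genes called in both knockout groups against WT SP numbered 8, all in the same direction: Cd163l1, Gpm6b, Gtsf1 and Xist higher, and Ddx3y, Eif2s3y, Kdm5d and Uty lower. Independent lists of these sizes would share 0.229 higher and 0.252 lower genes. In 100 simulations of unchanged groups against the same WT SP libraries, 0.0400 genes were shared on average. These reference values make no allowance for sex. Xist and the lower genes, all Y-linked, part every knockout library from every wild-type library, so their sharing cannot be told from sex. Without them Cd163l1, Gpm6b and Gtsf1 remain, all higher, and sex is not excluded there either. The fold changes correlated at 0.391 across genes, which are not independent replicates, against 0.408 in the simulations, and their covariance was 0.173 against 0.0780. With the WT SP libraries split into separate pairs, the correlation ran from -0.10 to 0.33 over the 6 splits and the covariance from -0.0651 to 0.155. After scaling 13 higher and 4 lower genes were shared, with a covariance of 0.183 against 0.0525. Without KO SP replicate 1, 5 genes were shared.

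The H3K9me3 peak lists asked whether the mark differed between genotypes. The lists held 85960 and 23304 peaks in WT replicates 1 and 2 and 111149 and 154997 in KO replicates 1 and 2, covering 72.2, 16.4, 81.6 and 129 Mb. The KO lists covered 61.0 Mb more on average, and 12.1 Mb more when the 23304 highest-scoring peaks of each list were compared. Those top peaks covered 35.4 and 16.4 Mb in WT and 31.6 and 44.4 Mb in KO, so the genotypes overlapped. They were the whole list of WT replicate 2. Over all peaks the difference was 88.9 and 33.1 Mb without WT replicates 1 and 2, and 84.8 and 37.3 Mb without KO replicates 1 and 2. Steps in the deposited scores put the relative depth at 1, 0.343, 1.11 and 1.16 in the same order. With 2 against 2 libraries no exact test can reach an adjusted threshold, so these are descriptions of the libraries. The Jaccard index (shared over joint covered bases) was 0.118 between the WT lists, 0.176 between the KO lists, and 0.133, 0.133, 0.0716 and 0.0486 between genotypes, so that the within-genotype mean exceeded the between-genotype mean by 0.0503 (0.116 and 0.0428 without WT replicates 1 and 2, 0.0269 and 0.0155 without KO replicates 1 and 2).

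At Cd4, whose start lies at position 124838227 of chromosome 6 (mm9, minus strand), all 4 lists held an intergenic peak upstream of the start, centred at -1208 and -1288 bp in WT and at -1162 and -1047 bp in KO, with scores of 19.5, 12.6, 22.8 and 23.8. Scores of different lists compare only roughly. Within their own lists these lay at percentiles 73.5, 14.4, 91.7 and 90.3. An intron peak was centred 8145 bp into the gene in WT replicate 1 (score 37.3, percentile 90.6), 2315 bp in WT replicate 2 (22.1, percentile 67.9) and 8210 bp in KO replicate 2 (14.4, percentile 74.3), and KO replicate 1 listed none. The share of the 5 kb either side of the start that was covered was 6.51% and 11.3% in WT and 6.29% and 7.53% in KO.

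**Figure D4:**
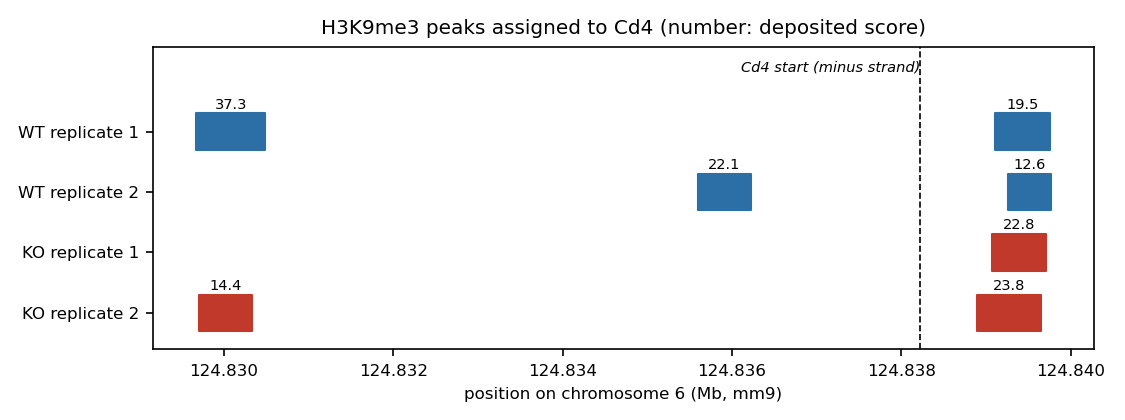
Boxes mark the H3K9me3 peaks assigned to Cd4 in each of the 4 lists (blue, WT; red, KO), drawn to scale along chromosome 6 in Mb of mm9, with the deposited score above each and the gene start as a dashed line. Each list has a peak upstream of the start, centred at -1288 to -1047 bp, and 3 of the 4 have a peak in an intron.

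Of 61 genes of the helper lists that could be placed, Ccr6 and Ccr8 were covered more in both WT lists and Slamf6, a receptor of the follicular helper list, more in both KO lists. Around the start of Ccr6 (chromosome 17, 8428908) the covered share was 30.8% and 11.01% in WT and 5.63% and 5.01% in KO. Around the start of Ccr8 (chromosome 9, 120001251) it was 19.7% and 21.3% against 9.32% and 11.97%, and at Slamf6 (chromosome 1, 173847668) 4.29% and 0% against 6.39% and 7.17%. Chance would put each genotype above the other at 16.7% of genes without ties. Over all 13187 placed genes KO lay above at 8.53% and WT at 4.63%, since many genes had no peak in any list. Among the 61 helper list genes KO lay above at 1.64% and WT at 3.28%, both below the shares of all placed genes. By limma 0 of 5967 genes with a peak differed in covered share, 779 had an unadjusted p under 0.05, and the smallest adjusted p was 0.307. Even Gm13251, covered at 10.02% and 5.01% in WT and 52.7% and 56.6% in KO, had only that adjusted p. The lack of calls is therefore no evidence that the mark was unchanged. Leaving out WT replicate 2, KO replicate 1 or KO replicate 2 gave 1253, 1307 and 874 calls, mostly lower without the first and mostly higher without the others. Ccr6 and Ccr8 were among the genes whose RNA rose in KO DP, but their RNA and H3K9me3 came from different cells, grown differently.

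The 198 placed genes that rose in KO DP had a mean KO minus WT difference of -0.724 percentage points, against -0.285 in 10000 random lists matched on expression (percentile 5.14). The mean was 0.0971 without WT replicate 1 (random lists 0.520, percentile 6.15) and -1.55 without WT replicate 2 (random lists -1.09, percentile 8.91). With windows of 2 kb either side it was -0.956, against -0.834 in the random lists (percentile 36.8), and with equal numbers of top peaks -1.21 against -0.699 (percentile 2.71). For the 287 placed genes that fell the mean was -0.265 (percentile 77.6). It was 0.320 and -0.850 without WT replicates 1 and 2 (random lists 0.334 and -1.16), and -0.100 and -0.429 without KO replicates 1 and 2 (random lists -0.387 and -0.444). With 2 kb windows it was -0.274 against -0.875 in the random lists (percentile 98.8), and with equal numbers of top peaks -0.539 against -0.780 (percentile 88.9). For 8 helper lineage genes it was -0.248 (percentile 53.6), and -0.546 and 0.05 without WT replicates 1 and 2 (random lists 0.212 and -1.10). Its sign turned with 2 kb windows (0.359 against -0.901, percentile 87.2) and with the upper 50% of scores (0.0650 against -0.289, percentile 63.2). The medians were 0 in these lists and in the random ones, so they could not tell them apart. Among the largest differences over single genes, none of which passed the test, were those at Rn45s, the ribosomal RNA precursor (51.4% and 51.1% covered in WT, 0% and 5.01% in KO) and at the keratin-associated gene Krtap8-1 (0% and 0% in WT, 29.4% and 33.8% in KO).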

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

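The tests of the low totals and of the peak regions, and those on Y-linked genes, on the furthest falls and on the rises, the limit to splits that part the pairs and the use of Cd8a, were chosen only after the result was seen; the test of sex in other libraries, the test of the median fall and the splits were written down first.

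KO DP replicates 3 and 4 had low FPKM totals and lay below the other libraries over most genes, while the other 2 libraries of that group did not. Lower sequencing depth was excluded, since the lower of their relative depths was 1.14, within the range of the other libraries. A few genes taking most of the FPKM was excluded too, since the 10 most abundant genes held at most 11.5% in these 2 libraries, against up to 15.1% in the others. Reads spread over the genome outside expressed genes may account for the low totals: the olfactory receptor mean of the lower of the 2 was 7.12 times the highest of the other 8, a test that could have come out the other way. The design gives no biological explanation for a difference between libraries of 1 group, so none was tested.

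All 4 Y-linked genes lay above every knockout library in every wild-type library, which a difference in the sex of the donors could explain, and genotype cannot be told from sex for such genes. For the changes between KO DP and WT SP, sex was excluded as the whole cause over a set of 526 genes. These were called after scaling in a fit of KO DP replicates 1 and 2 and WT SP alone, the sex-linked ones left out. At these genes KO DP replicates 3 and 4 differed from KO SP, which has the same Xist and Y-linked pattern. The median difference was 1.04 in the same direction (quartiles 0.57 and 1.56, with 92.8% of genes of the same sign). Between KO SP and WT SP no such test was possible. Sex cannot be told from genotype there, at Cd163l1, Gtsf1, Gpm6b and Gabrr2 as well. The labels give the KO DP cells as CD4+CD8+, which a pure selection would keep free of conventional CD4+ T cells, but how the cells were selected is not given in the sources used here. Whether such cells could account for most falls stays open. The median called fall after scaling, -0.85, lay within that of Cd8b1 (-0.89 ± 0.15) but more than 2 SE beyond that of Cd8a (-0.48 ± 0.15), and CD4+ T cells lack both. They do not account for the 80 of 869 falls that lay beyond Cd8b1 with their bounds apart (Igfbp4, Plac8 and Aqp9 among them), if the CD8 cells were otherwise unchanged. The 80 also held the 4 Y-linked genes, and Surf2, Cd72 and Pusl1, whose listed zeros may be failed estimates. For the rises the tables cannot tell such cells, possibly with a Th17 or regulatory character, from double-positive cells that took up helper genes: the value of -0.89 for Cd8b1 would be seen with either. The description numbers were taken to pair the samples, though the check could not tell pairing from the number range. On that reading only 8 splits of the 8 libraries part all 4 pairs, too few for a share under 0.05. The real one gave 881 calls and the highest other 2. The 35 splits in all include those that keep pairs together, of which the one that follows the number range gave 245 (811 after scaling).

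Some of the highest-scoring regions of the WT peak lists, major satellite sequence on chromosome 2 among them (scores of 516902 and 2.39e+06), were not covered in the KO lists, although 85% to 92.3% of the top 1000 WT peaks were. Of the top 50 peaks, 74% and 76% of WT replicate 1 and 82% and 78% of WT replicate 2 were covered in KO replicates 1 and 2. The other WT list covered 88% and 90% of them. In the reverse direction, WT replicates 1 and 2 covered 84% and 82% of the top 50 peaks of KO replicate 1. Of those of KO replicate 2 they covered 82% and 72%, and the other KO list covered 86% and 90%. Top peaks missing from lists of the other genotype were therefore not limited to WT. Loss of H3K9me3 from satellite could be the cause and stays open: among equal numbers of top peaks satellite held 0.549% and 0.390% in WT and at most 0.386% in KO, with overlapping intervals. That share counts a weak peak like a strong one, so it cannot show a loss of signal. Of the score sum of a list, satellite held 24.3% and 81.8% in WT and 0.385% and 0.314% in KO. Multi-copy sequence that entered the WT and KO lists differently could account for it too: the ribosomal gene Rn45s, which is no satellite, reached 33534 and 21418 in WT and at most 17.0 in KO. The step that did so is not known, and no biological explanation beyond the first was tested.

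Other values were far from the rest of their group by Dixon's test, in FPKM: 13 of 140 groups over 68 genes and 2 library measures, where chance flags about 1 in 20 groups, here 7. In WT SP replicate 2 these were Ctla4 (11.8, others 0.513 to 0.961), Il1r2 (0.775, others 0 to 0.0810), Satb1 (54.6, others 107 to 115), Tff1 (1.36, others 0 to 0.129), Tnfrsf4 (7.52, others 2.12 to 2.23) and Zbtb7b (0.853, others 0.214 to 0.304). In WT SP replicate 1 they were Ccl1 (1.84, others 0), Ccr4 (0.375, others 0.0899 to 0.135) and Folr4 (1.63, others 0.353 to 0.504). In KO DP they were Klra3 in replicate 1 (1.14, others 0.0223 to 0.188), Il21 (19.1, others 2.80195 to 4.65) and Xist (4.58, others 2.59 to 2.77) in replicate 2, and Pusl1 in replicate 4 (8.83, others 0).

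The X chromosome, which the covered lengths and overlaps above include, held 3.43% of the covered length in WT H3K9me3 replicate 1. In the other 3 lists it held 0.215% to 0.732%. On the Y chromosome WT replicate 1 covered 0 Mb, against 0.0025 Mb in WT replicate 2 and 0.0090 and 0.0082 Mb in KO replicates 1 and 2. Whether the donors of these libraries differed in sex, within WT as well, was not tested.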

How the results depend on the processing

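Of 123 gene results, 98 were called, and 2237 of the 2524 values of called genes over 28 settings kept direction and call; none of the called genes turned. Over all named genes 2742 values were the same, 75 stronger, 287 weaker and 39 turned, all of these among uncalled genes; of the list calls 710 were the same, 103 weaker and 2 turned. The cause was not tested for any change below unless its construction shows it (fewer genes, fewer libraries). The restriction of KO DP and the scaled fits with a block were chosen after seeing the data. The gene body alone was not run, for want of mm9 gene models. Where leaving out a library left 1 in a group, it was assumed to vary like the other groups. Among the named genes and the lists, blocking on the description number changed no other call than that of Cd8b1; over all genes it shared 798 calls with the 881. KO DP and KO SP share the title numbers 738 and 739 (correlations 0.143 and 0.0908), only 2 pairs. In both, the KO SP library of the same number was the better correlated of the 2. The counts given first used no such pairing, though it stays possible.

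In the order KO DP against WT SP (881), KO SP against WT SP (13), KO DP against KO SP (231) and genes shared (8), the counts that moved were as follows. A filter of 5 FPKM gave 519, 5 and 4 shared, with fewer genes tested; no filter gave 113 for KO DP against KO SP. Scaling to an equal sum gave 1852, 28, 493 and 24, median ratios 1952, 20, 606 and 17, and quantiles 2001, 524 (KO DP against KO SP) and 16 shared. Array weights gave 3801, 260, 3895 and 192. Fitting only the 2 groups compared gave 556, 27, 86 and 19. A block for the number range gave 2123, 37, 468 and 23, and with median ratios 3082, 25, 547 and 21. The description number gave 1375, and with median ratios 1850. The title number gave 570 for KO DP against KO SP as a random term and 4587 with the 2 pairs alone. Titles 738 to 741 alone gave 6015, 63, 5964 and 42, and titles 34 to 37 alone 73. KO DP replicates 1 and 2 alone gave 29, 460 and 22 for the last 3. Setting 2 WT SP libraries against each knockout group gave 6 shared genes, near the 8. A pseudocount of 0.1 (903, 14, 211) and no trend (863, 11, 231) kept the counts. Without any 1 library the counts ran from 308 to 1211, 9 to 16 and 21 to 401, and 5 to 11 were shared.

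Of 63 list tests 31 were called (26 up, 5 down), 26 to 37 without any 1 library, and 0 with an estimated correlation, where the lowest adjusted p was 0.165. The erythroid list of KO DP against KO SP turned with the 2 pairs (adjusted p = 0.529) and with median ratios and the range block (0.378).

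These uncalled genes turned. For KO SP against WT SP, Cd8b1 was -0.0126 with equal sums, -0.0461 with median ratios, -0.0103 with array weights, -0.0475 in titles 738 to 741 and -0.0669 with median ratios and the range block; Cd8a was -0.0051 and -0.0118 in the last 2. With the range block Runx3 was 0.0837, Cd4 0.27, Zbtb7b 0.19 and Gata3 0.32; in titles 738 to 741 Runx3 was 0.0459 and Cd4 0.0229; with median ratios and the range block Cd4 was 0.0028 and Zbtb7b 0.0120. Gata3 was 0.0672 with title number as a random term, 0.0129 without KO SP replicate 2 and 0.0089 without WT SP replicate 2, and -0.0776 to 0.0129 over all fits without 1 library. For KO DP against KO SP, Runx3 was 0.29 with equal sums and with quantiles, 0.28 with median ratios, 0.24 with array weights and with KO DP limited, and 0.0491 with median ratios and the range block. Ehmt2 was -0.17 with the range block, -0.40 with the 2 pairs and in titles 738 and 739, and -0.0016 and -0.0582 without KO DP replicates 1 and 2, and -0.0582 to 0.47 over all fits without 1 library. Gata3 was -0.27, -0.59 and -0.59 in the same settings, -0.0177 with title number as a random term, and -0.16 and -0.13 without KO DP replicates 1 and 2, and -0.16 to 0.43 over all fits without 1 library. For KO DP against WT SP, Runx3 was 0.13 with array weights, and Gata3 -0.59 in titles 738 to 741 and -0.19 and -0.16 without KO DP replicates 1 and 2, and -0.19 to 0.40 over all fits without 1 library.

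For H3K9me3, the KO lists covered 61.0 Mb more, 41.0 Mb with the upper 50% of scores, 12.1 Mb with equal numbers of top peaks, and 33.1 to 88.9 Mb without any 1 library. With equal numbers of top peaks WT replicate 1 covered more than KO replicate 1 (35.4 against 31.6 Mb). The within minus between Jaccard difference was 0.0503, and 0.0155 to 0.116 without any 1 library. The shared share of peaks differed by 8.55 percentage points, and by 8.26 at 50% minimum overlap. Calls over genes were 0, and 0 to 1307 without any 1 library, where 1 group had a lone library. The mean difference at genes higher in KO DP was -0.724 percentage points, -0.956 with windows of 2 kb (random lists -0.834), -1.21 with equal numbers of top peaks (random lists -0.699) and -1.55 to 0.0971 without any 1 library. Depth limits low genes, and KO SP with 2 libraries leaves small changes unseen.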

Other observations

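WT SP replicate 2 was the highest of its group at 10 of the 11 tested genes of the inhibitory receptor list and the lowest at 1, Cd160 (32.0 FPKM, others 35.2 to 43.0). The genes below were chosen after their values were seen. Pdcd1 (PD-1) lay at 238 FPKM in WT SP replicate 2 and at 3.31, 2.34 and 1.41 in replicates 1, 3 and 4. Tox, a factor of exhausted T cells, lay at 148.5 against 10.7, 13.0 and 14.4 FPKM, Lag3 at 27.9 against 0.282, 0.162 and 0.309, Havcr2 (TIM-3) at 54.05 against 4.21, 1.78 and 1.68, and Tigit at 72.7 against 5.21, 0.942 and 1.65. In KO DP replicates 1 to 4 Pdcd1 lay at 138, 187, 75.7 and 48.7 FPKM and Tigit at 97.0, 148, 40.5 and 17.9, and in KO SP Pdcd1 lay at 11.6 and 10.4. None of these 5 genes was called between KO DP and WT SP as deposited; without WT SP replicate 2 all but Tox were.

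Zinc finger genes, a known target of H3K9me3, were nearest to 4.00% (95% interval 2.95% to 5.40%) and 3.90% (2.87% to 5.29%) of the 1000 highest-scoring peaks in WT replicates 1 and 2 and to 6.40% (5.04% to 8.09%) and 5.30% (4.07% to 6.87%) in KO replicates 1 and 2. Over all peaks of a list the share was 1.28%, 1.94%, 0.982% and 0.920%. Among the 23304 highest-scoring peaks of each list, endogenous retroviruses of the ERVK family held 11.5% and 9.34% in WT and 8.33% and 7.11% in KO. ERV1 held 4.58% and 2.72% in WT and 2.88% and 2.44% in KO, values that overlapped. Families with both KO lists above both WT lists included MaLR with 9.53% and 8.79% in WT and 10.9% and 10.2% in KO, ERVL with 0.820% and 0.790% against 1.52% and 1.58%, and the less common MER1_type, MIR and L2. Simple repeats held 10.05% of the peaks of WT replicate 2 and 2.46%, 2.06% and 2.37% of the top peaks of WT replicate 1 and KO replicates 1 and 2. Intervals treat peaks as independent, which neighbouring peaks are not.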
